A study of Mus musculus with 2 samples.

How the data were processed

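ChIP-seq with an antibody to H3K9me3 was done on neural tube of embryonic day 14.5 mice, with 2 biological replicates of pooled embryos (24 and 34) and 2 technical replicates in each, per the labels. The labels give a size range of 300 to 500 bp. Analysis started from 4 deposited peak lists. Per the file headers, 1 list was made from replicate 1, 1 from replicate 2 and 1 from both pooled, all on mm10. The replicated list was derived from these 3 per the file headers, by a rule that is not stated there. Tested on the files, all of its 6326 rows were rows of the pooled list. The file headers also show that replicate 1's peaks were made with 2 files from outside the series and replicate 2's with 1 of them. The kind of these files is not stated. The aligner, the peak caller, their versions and filters, and the number of reads are not given in the sources used here.

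Each deposited list has a fold enrichment, a ratio of signal to background as the authors' caller gave it, in its seventh column. The deposited lists also have the −log10 p and −log10 q of each peak and the offset of its summit. The deposited display score of each peak was not used. The lists have no header line, and these meanings come from the narrowPeak format and the range of the values. The lowest −log10 p in the 4 lists lay between 2.00 and 2.05, so the lists contain weak calls. Peaks with −log10 q of at least 2 (q of at most 1%) made up 5.22% of replicate 1's list, 13.7% of replicate 2's, 14.3% of the pooled and 34.9% of the replicated list. Fold enrichment was used to describe and rank peaks within a list. Fold values were coarse: the 5 commonest values accounted for 42.3% of replicated peaks and 65.6% of replicate 1's peaks. Because depth was unknown, the absence of a peak was not read as absence of the mark. Binomial intervals on shares of peaks are exact (Clopper-Pearson, 95%) and cover counting error only, and neighbouring peaks are not independent.

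Genes were taken from GENCODE M21 and sequence from GRCm38, the build named mm10, so coordinates were used without conversion. Tests used chromosomes 1 to 19, X and Y. Peaks on other sequences (207 of the replicated list) were left out of the tests. They were kept in descriptions of whole lists and in the overlap of the replicated and pooled lists with each replicate's list. A gene was counted as marked when a peak shared at least 1 bp with its body or the 2 kb upstream of its TSS. A summit was assigned to a promoter (within 2 kb of a protein-coding TSS), then exon, then intron, then outside protein-coding genes. The 24 gene lists, 13 defined by symbol pattern and 11 by symbol, were fixed before the data were examined, together with the tests and the rule for named genes. Non-coding members of the lists were added to the 21938 protein-coding genes.

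Chance was measured by rotating all peaks of a list by a random distance along each chromosome, between its first and last called base, which keeps peak widths and clustering. There were 10000 rotations (1000 for sequence content and for replicate overlap at 50% of the shorter peak). Two-sided p-values were 2 times the smaller tail, at most 1, with smallest values of 0.0002 and 0.002. The Benjamini-Hochberg adjustment was over the 24 lists. Positions within genes were compared by a permutation test of medians with 100000 resamples. Rho was given a 95% interval by resampling 1 Mb blocks 1000 times. With 1 group there was no contrast between conditions, no p across replicates and no analysis by pairs. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

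The statistics were tested on simulated data. In 60 simulated sets over 21946 genes, a list of 200 genes of which 50 were given a peak had p under 0.05 in 100% of sets, and random lists did in 1.67%. For summit classes, rotated peaks gave p under 0.05 in 10% of sets, so p-values near the threshold there deserve caution. For replicate overlap, unrelated sets gave p under 0.05 in 5% and related sets in 100%. For the median position the shares were 5% without and 100% with a shift. Null peaks were made by rotation, as in the tests themselves, null gene lists were random genes and simulated positions were uniform values. Tandem arrays and genes that share a summit were not simulated, so the tests are not checked for those.

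Named genes followed the fixed rule. It takes the 12 protein-coding genes with the highest fold enrichment of a replicated peak also overlapped in both replicates' lists (for a peak in several genes, the gene with the nearest TSS), the 8 with the most covered gene body, and up to 4 members per list with the highest fold. The 5 peaks of highest fold and the 10 densest 1 Mb windows were named by position. Genes named outside the rule are Zrsr1, Nespas, Peg3, Usp29, Klra17, Drg1, Gm26917, CT010467.1 and Pcdhac1. So are the 4 protocadherins without a peak and the families in the closing section. They were chosen after their values were seen.

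Alternatives fixed beforehand were each replicate's own list in place of the replicated list, the pooled list, a q of at most 1%, other overlap criteria, lists of equal length, merged rows, removal of the sex chromosomes, 500 kb windows, a 1 kb promoter, windows of 2 kb around the TSS, the 1000 peaks of highest fold, random genes matched on length (10000 draws), Fisher's exact test, the mean over a gene's summits, other genes matched on length, and 200 bp around summits. Added after the data were seen were the replicated peaks that share at least 50% of either peak with both replicates' lists, and the removal of summits inside Zfp-named and protocadherin genes.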

Results

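Trimethylation of histone H3 at lysine 9 (H3K9me3), a chromatin mark found over heterochromatin and stably silenced genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the neural tube of mouse embryos at embryonic day 14.5. The neural tube is the embryonic precursor of the brain and spinal cord. There was 1 group with 2 biological replicates. Replicate 1 was a pool of tissue from 24 embryos and replicate 2 a pool from 34 embryos, with both sexes mixed in each pool. No other tissue, age or mark was part of the series, so the comparisons set peak positions against chance placement on the same chromosomes and replicate against replicate. The number of reads per library was not given in the sources used here, and the depth is therefore unknown. Replicate 1 had 30878 peaks covering 7.92 Mb, replicate 2 had 7946 peaks covering 2.53 Mb, and the 2 replicates pooled had 17942 peaks covering 5.39 Mb. The authors' replicated list, whose 6326 peaks were all rows of the pooled list, covered 2.67 Mb with a median width of 333 bp and a median fold enrichment of 3.44. Fold enrichment is the authors' value for each peak over the background of their peak caller. All gene-level results are for the replicated list unless another is named, and all coordinates are on mm10.

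The first comparison asked which genes carried the mark. Of 21938 protein-coding genes, 1203 (5.48%) had a replicated peak in the gene body or within 2 kb upstream. Of 24 gene lists chosen before the data were examined, 4 had more members with a peak than chance placement gave. These were the clustered protocadherins, the imprinted genes, the zinc finger genes named Zfp, and the vomeronasal receptors. No list lay below chance, but for most lists the test could not have shown this. The lower end of the central range of chance placement was above 0 for only some lists. These were the Zfp-named, olfactory receptor, vomeronasal receptor and cytochrome P450 genes, at 10, 6, 4 and 1 members. For every other list that lower end was 0, so even a count of 0 could not pass. The test was a circular permutation that rotated the peaks along each chromosome 10000 times, was two-sided, and was adjusted by the Benjamini-Hochberg method over the 24 lists. It compares regions with chance placement in these libraries and not 2 conditions, and neighbouring genes that share a peak are not replicates. In the single replicates' own lists the ratio to chance was smaller, from 2.24 to 6.63-fold for protocadherins, 2.41 to 5.74 for imprinted genes, 1.85 to 3.82 for Zfp-named genes and 1.83 to 2.98 for vomeronasal receptors. The counts hardly fell or rose: replicates 1 and 2 marked 53 and 52 protocadherins, 35 and 28 imprinted, 167 and 105 Zfp-named and 106 and 51 vomeronasal genes. Chance placement of these longer lists also gave more, at 23.7 and 7.85 protocadherins against 5.68 for the replicated list. The smaller ratios therefore do not show a weaker mark in each replicate.

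**Figure D1:**
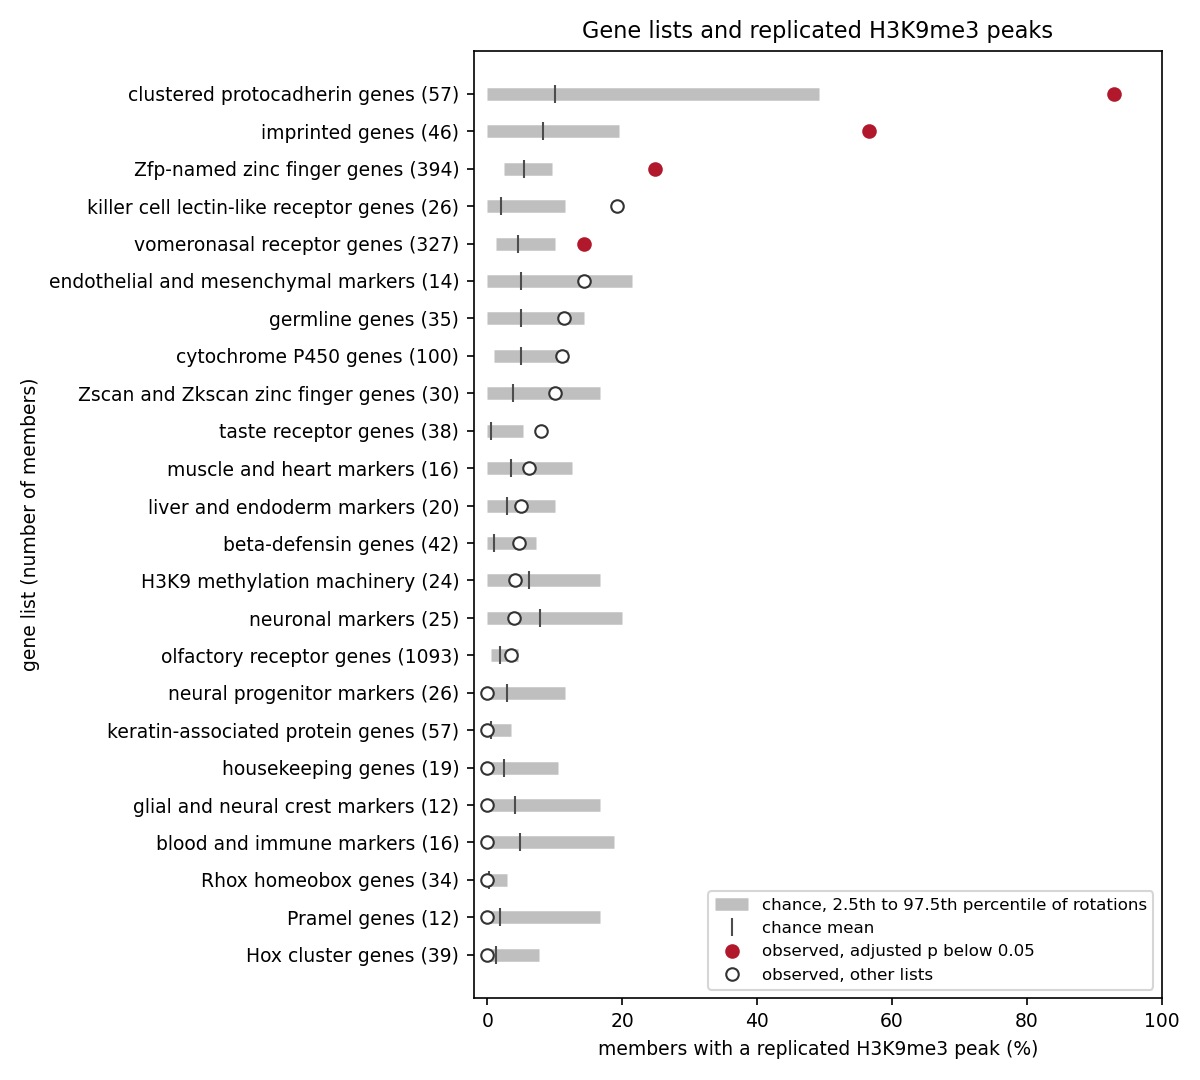
Percentage of the members of each of 24 gene lists with a replicated H3K9me3 peak in the gene body or within 2 kb upstream (circles), beside the mean (tick) and the central 95% (grey bar) of 10000 rotations of the peaks. Filled circles mark the 4 lists with an adjusted p under 0.05, at 93.0% of clustered protocadherins, 56.5% of imprinted genes, 24.9% of Zfp-named genes and 14.4% of vomeronasal receptor genes.

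The clustered protocadherins, cell-surface adhesion molecules of neurons encoded in the alpha, beta and gamma arrays on chromosome 18, had the highest share. Of 57 genes, 53 (93.0%) had a replicated peak against 5.68 by chance, a 9.33-fold excess (permutation, adjusted p = 0.0016). Per array, 13 of 14 alpha genes, 22 of 22 beta genes and 18 of 21 gamma genes had a peak, where 2 alpha gene models share the symbol Pcdha11 and count apart. The 4 genes without a peak were Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, C-type genes at the ends of the alpha and gamma arrays. Pcdhac1, also C-type, had 3 peaks, the highest at 4.15. The 4 were picked out after their values were seen. A peak lay within 2 kb of the transcription start site (TSS) in 50 of the 57 genes, against 0.633 by chance. The array genes overlap one another, so 205 distinct peaks at a single locus underlie the count. The alpha array (18:36930184-37187661) held 71 peaks with a median fold enrichment of 3.79, the beta array (18:37264938-37524479) 66 peaks with a median of 3.48, and the gamma array (18:37661793-37841873) 81 peaks with a median of 4.15. The highest peaks, both at 6.28-fold, had their summits in coding exons of Pcdhga11 (18:37755080-37758577) and Pcdhga12 (18:37765684-37768373). Pcdhga1 and Pcdhga10 also span the first of these, where its summit is intronic. The 8 protein-coding genes with the most covered sequence were all models across this locus. Gm42416, Gm37013 and Gm37388, which extend from the alpha into the gamma array, had 134461, 127987 and 125864 bp covered. Pcdhga1, Pcdhga2, Pcdhga3, Pcdhgb1 and Pcdhga4 followed, with 56957 to 68833 bp. Restricted to peaks present in both replicates' own lists, an alternative added after the data were seen, 46 genes had a peak (permutation, adjusted p = 0.0016).

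**Figure D2:**
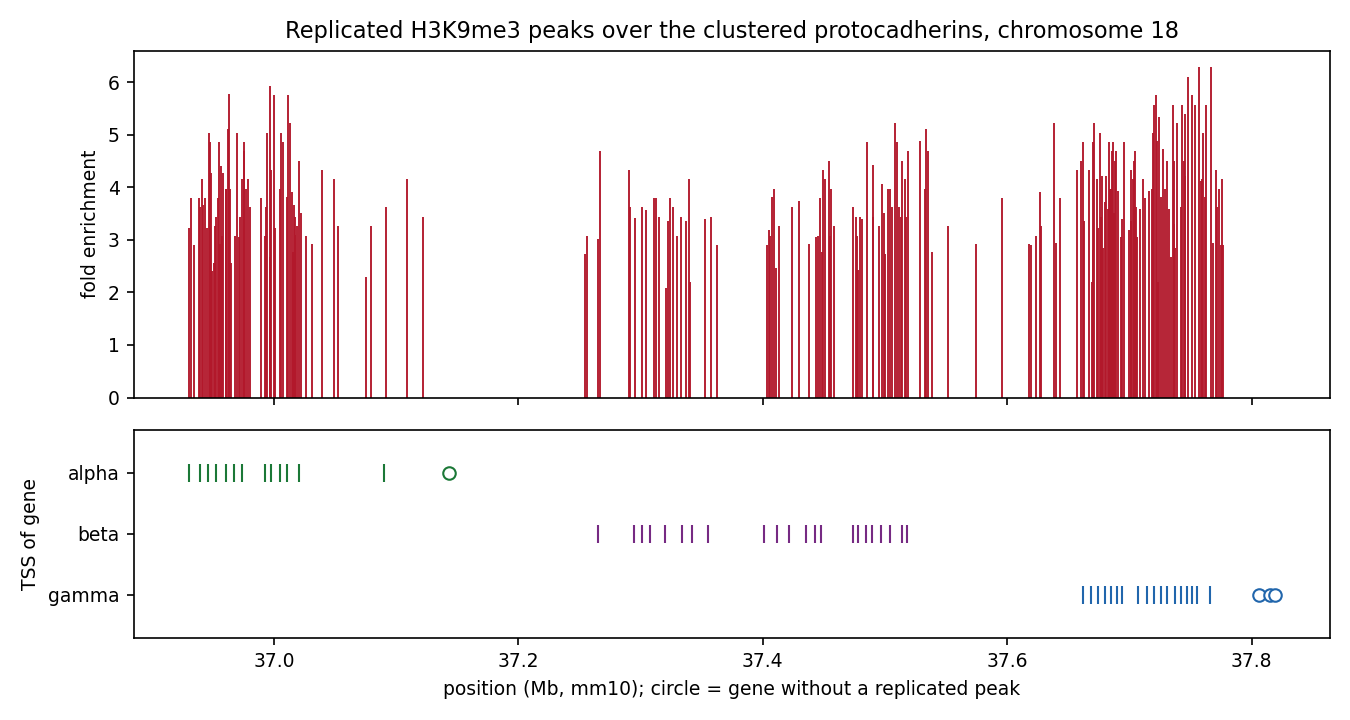
Replicated H3K9me3 peaks over the protocadherin arrays on chromosome 18 (mm10), with the position in Mb on the horizontal axis and each peak's fold enrichment as the height of a line in the upper panel. The lower panel places the TSS of each alpha, beta and gamma gene, with a circle for the 4 genes without a replicated peak, which lie at the distal end of the alpha and gamma arrays.

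Zinc finger genes named Zfp, most of which encode DNA-binding proteins and many of which stand in tandem clusters, had a peak in 98 of 394 cases (24.9%) against 21.4 by chance, a 4.59-fold excess (permutation, adjusted p = 0.0016). These genes lay on 16 chromosomes and held 405 distinct peaks. Chromosome 7 contributed 23 of its 92 Zfp-named genes, chromosome 17 contributed 12 of 46, chromosome 13 contributed 10 of 36 and chromosome 4 contributed 9 of 30. The 4 members with the highest fold enrichment were Zfp68 (7.0, 5:138604854-138607319, coding exon), Zfp945 (6.46, 17:22851015-22852841, coding exon), Zfp981 (6.28, 4:146534090-146534485, intron) and Zfp27 (6.11, 7:29894106-29895928, coding exon). Within 2 kb of the TSS alone the excess was absent, with 5 genes against 5.02 by chance (permutation, adjusted p = 1). Among peaks in both replicates' own lists, 81 Zfp-named genes had a peak (7.85-fold over chance, permutation, adjusted p = 0.0016). The separate list of Zscan and Zkscan zinc finger genes did not pass, with 3 of 30 members carrying a peak (permutation, adjusted p = 0.55). They were Zkscan7, Zscan20 and Zscan18, with fold enrichments of 3.79, 3.79 and 2.93.

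Where the mark lay within Zfp-named genes was compared with its position in other genes. In the 98 Zfp-named genes with a summit in the gene body, the highest summit had a median relative position of 0.826 (interquartile range 0.672 to 0.923), where 0 is the TSS and 1 the gene end. In 1046 other protein-coding genes the median was 0.473 (0.231 to 0.759). The difference of 0.353 had p = 1e-05 in a two-sided permutation test with 100000 resamples, the smallest p these can give. The test treats genes as independent, but overlapping genes such as the protocadherins share a summit and many Zfp-named genes are neighbours. Its p can therefore be too small. The highest summit lay in an exon of the gene in 66 Zfp-named genes (67.3%, exact 95% interval 57.1 to 76.5%) and in 187 other genes (17.9%, 15.6 to 20.3%). It lay beyond the middle of the gene in 84.7% of Zfp-named genes and 47.3% of the others. These shares were not matched on gene length, and no exon share expected by chance was measured for these genes. Against other genes of matched length the difference was smaller, at 0.192 (permutation p = 6e-05).

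**Figure D3:**
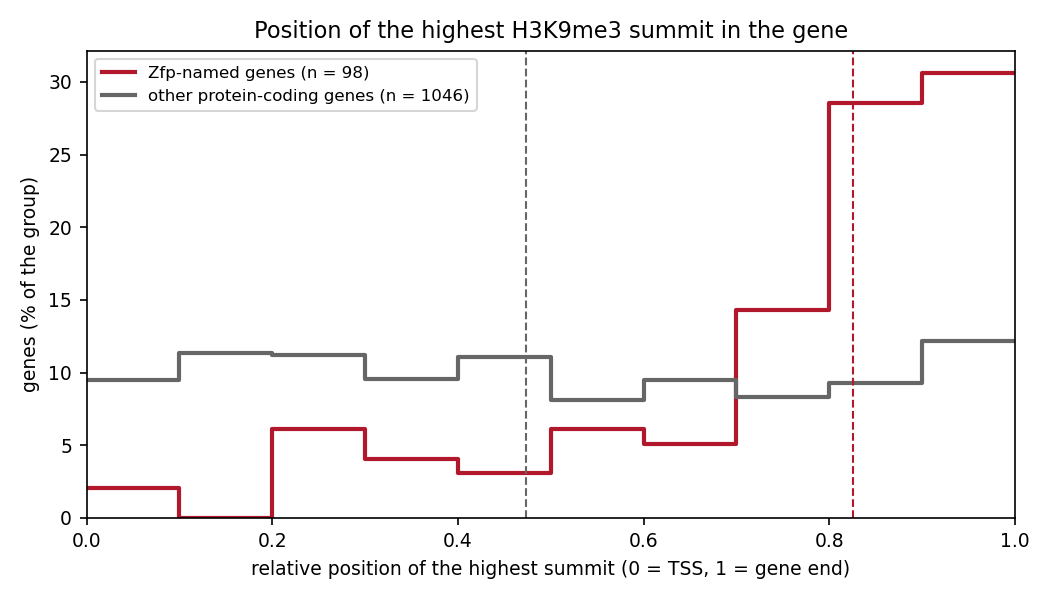
Relative position of the highest replicated H3K9me3 summit along the gene, from the TSS at 0 to the gene end at 1, as the percentage of genes per 0.1 of gene length. The red line is for 98 Zfp-named genes and the grey line for 1046 other protein-coding genes; dashed lines mark the medians of 0.826 and 0.473.

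Imprinted genes, which are expressed from the maternal or the paternal allele, had a peak in 26 of 46 cases (56.5%) against 3.79 by chance, a 6.85-fold excess (permutation, adjusted p = 0.0016). The 26 genes share peaks where they overlap, and 39 distinct peaks on 8 chromosomes underlie the count. Grb10 (11:12026542-12026831, intron) and Mest (6:30739197-30739492, intron) had the highest fold enrichment at 4.33. Commd1 and Gnas followed at 3.97. The Commd1 peak (11:22971785-22972752) lay in an intron of that gene and in the 5′ untranslated region (UTR) of Zrsr1, which is encoded inside it. The Gnas peak (2:174284693-174284992) was in a coding exon 519 bp from the TSS and also inside Nespas. A peak with its summit 219 bp from the TSS of Peg3 and 366 bp from that of Usp29 (7:6729724-6730370) had a fold enrichment of 3.97. Counting only peaks within 2 kb of the TSS, 11 imprinted genes were marked against 0.631 by chance (permutation, adjusted p = 0.0024). Within this fixed list fold enrichments were modest, with a highest peak per gene between 2.58 and 4.33. For 13 of the 26 genes that peak overlapped a peak in both replicates' own lists. Imprinted genes outside the list were not counted, so the range does not describe imprinted genes in general. With peaks in both lists alone, 19 imprinted genes were marked (permutation, adjusted p = 0.0016).

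Vomeronasal receptor genes, which encode pheromone receptors of sensory neurons, had a peak in 47 of 327 cases (14.4%) against 14.7 by chance, a 3.19-fold excess (permutation, adjusted p = 0.0144). The highest were Vmn1r66 (7:10276456-10276781) and Vmn2r105 (17:20204971-20205200) at 4.50, then Vmn1r75 (7:11873493-11873870) and Vmn2r59 (7:42016588-42016818) at 4.33. The excess did not pass among peaks with a q of at most 1% (15 genes, 2.68-fold, permutation, adjusted p = 0.356), among the 1000 peaks of highest fold (8 genes, 2.91-fold, adjusted p = 0.572) or within 2 kb of the TSS (17 genes, 3.14-fold, adjusted p = 0.159). The other chemoreceptor lists did not pass in the main test. Olfactory receptors had a peak in 39 of 1093 genes against 21.1 by chance (permutation, adjusted p = 0.448), led by Olfr1469, Olfr362 and Olfr849 at 4.50 and Olfr1349 at 3.97. Their result varied: replicate 1's own list put them above chance (187 genes, 1.92-fold, permutation, adjusted p = 0.006), Fisher's exact test against all other genes put them below other genes (adjusted p = 0.0159), and random genes of matched length put them above (adjusted p = 0.0151). Taste receptors had a peak in 3 of 38 genes, all in one array on chromosome 6, with Tas2r107 at 3.62, Tas2r106 at 3.44 and Tas2r104 at 3.08 (permutation, adjusted p = 0.0605). They passed within 2 kb of the TSS (4 genes, permutation, adjusted p = 0.0408) and in replicate 1's own list (9 genes, adjusted p = 0.0176). No taste receptor had a replicated peak at a q of at most 1%.

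Germline genes, which are silent in most somatic tissues, had a peak in 4 of 35 cases against 1.76 by chance (permutation, adjusted p = 0.472). In 3 of them the summit lay close to the TSS. Those were Mael (12 bp from the TSS, fold 3.08), Dazl (101 bp, fold 3.07) and Ddx4 (465 bp, fold 2.93), and in Tdrd6 the summit was in a coding exon (fold 3.62). The list passed in the pooled list (12 genes, permutation, adjusted p = 0.0202), in replicate 2's own list (8 genes, adjusted p = 0.0317) and within 2 kb of the TSS (3 genes, adjusted p = 0.0408). It had no member with a replicated peak at a q of at most 1%.

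Lists for the cell types of the neural tube had few or no members with a replicated peak. None of 26 neural progenitor markers, 12 glial and neural crest markers or 39 Hox cluster genes, which pattern the body axis, had a peak. Of 25 neuronal markers only Gad2, an enzyme of GABA synthesis, had a peak, at a fold of 2.90 in an intron. That peak was a weak call, with a −log10 q of 0.527 and no counterpart in replicate 2's own list. These counts depend on the list: replicate 1's own list marked 3 neural progenitor, 2 glial and neural crest and 7 neuronal markers, and replicate 2's marked 0, 0 and 3. Chance placement gave between 0.474 and 1.97 members for these 4 lists, so a count of 0 could not pass the test for any of them. Among markers of other tissues, none of 16 blood and immune markers had a peak, against 0.764 by chance, where a count of 0 could not pass. Pdgfrb at 4.86 and Tek at 3.44 were the endothelial and mesenchymal markers with a peak, out of 14. Cyp3a11 was the 1 of 20 liver and endoderm markers, at 4.15. Of 16 muscle and heart markers only Ttn, the giant sarcomere protein titin, was marked, by 17 peaks covering 7905 bp, the highest at 4.33 in a coding exon. Replicate 1's own list marked 6 blood and immune and 7 endothelial and mesenchymal markers, and replicate 2's marked 1 of each. None of the 4 lists of other tissues passed (adjusted p of 0.59 to 1). No housekeeping gene of 19 had a peak, against 0.456 by chance, so a count of 0 could not pass. Of 24 genes of the H3K9 methylation machinery, Fam208a, a subunit of the silencing complex HUSH, had a peak 855 bp upstream of its TSS at 2.93. The peaks of Tek and Fam208a had a −log10 q of 1.38 and 1.09, short of a q of at most 1%.

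Gene families of other kinds did not pass in the main test either. Killer cell lectin-like receptors had a peak in 5 of 26 genes (permutation, adjusted p = 0.113), which were Klra7 at 3.44, Klra2 at 3.37, Klra6 at 2.94, Klra4 at 2.90 and Klra17 at 2.76. None of these 5 had a peak with a q of at most 1%, and the Klra6 peak had no counterpart in either replicate's own list. Cytochrome P450 genes had a peak in 11 of 100 (permutation, adjusted p = 0.35), led by Cyp2b9, Cyp2c38 and Cyp3a11 at 4.15 and Cyp2c29 at 3.79. By random draws of genes of matched length, both lists lay above chance (adjusted p = 0.0151 each), and the lectin-like receptors did by Fisher's exact test (adjusted p = 0.0494). Unlike rotation, these tests treat neighbouring genes as independent, so their p-values can be too small for tandem genes. Beta-defensins had a peak in 2 of 42 genes, Defb33 at 3.62 and Defb10 at 3.08 (permutation, adjusted p = 0.448), and none with a q of at most 1%. Keratin-associated protein genes (57), Rhox homeobox genes (34) and Pramel genes (12) had none. Chance placement gave 0.334, 0.0971 and 0.222, so a count of 0 could not pass.

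By fold enrichment, the strongest gene-associated peak present in both replicates lay in an intron of Sorcs1 (19:50385429-50385790), a sorting receptor of neurons, at 11.7 in the replicated list, 8.0 in replicate 1 and 12 in replicate 2. Klf14 (ENSMUSG00000073209.4), a transcription factor gene without introns, followed at 8.19, with 2745 bp of its body covered and the summit in coding sequence (6:30957184-30959236). Peak1, a pseudokinase gene, had a coding-exon peak at 7.06 (9:56260285-56260837). After Zfp68 came Gm10719 (9:3017379-3017716), the kinase gene Smok2b (17:13234520-13235191) and Tmem267 (13:119602325-119602654), all at 6.53. Zfp945, Pcdhga11, Pcdhga12, Zfp981 and Cdk8 (5:146261007-146261474, intron, 6.24), a kinase of the Mediator complex, completed the 12 genes of highest fold. No peaks were filtered out here as possible artefacts, so a high fold alone does not show a mark specific to the gene. At similar fold, −log10 p was 14.7 for Pcdhga11 and 75.9 for Cdk8. Of the 5 highest peaks of the list, the one on chromosome 7 (12010290-12010986), at 8.23, lay outside annotated genes. Peaks on Un_GL456393 (4982-5489), at 8.87, and 4_GL456216_random (33170-35634), at 8.42, were also among the 5. These sequences were not compared with genes, since genes were taken for the assembled chromosomes only.

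Peaks were concentrated in a small part of the genome. The densest 5% of 1 Mb windows, 137 of 2737, held 3591 of the 6119 peaks on assembled chromosomes (58.7%, exact 95% interval 57.4 to 59.9%), and 1254 windows (45.8%) held none. The densest window was 37 to 38 Mb of chromosome 18 with the protocadherins (18:37000001-38000000), with 121 kb covered by 193 peaks. It was followed by 1:88000001-89000000, which holds 9 Ugt genes of glucuronidation (60.1 kb), and 10:82000001-83000000 with 2 Zfp-named genes (46.8 kb). Of the other 7, 17:22000001-23000000 and 4:147000001-148000000 held 7 and 9 Zfp-named genes (40.5 and 31.2 kb). Window 7:12000001-13000000 held 7 Zfp-named and 12 vomeronasal receptor genes (39.3 kb), and 7:10000001-11000000 held 9 vomeronasal receptor genes (31.4 kb). Ceacam and Psg genes lay in 7:17000001-18000000 (32.6 kb), and cathepsin genes in 13:61000001-62000000 (31.7 kb). No protein-coding gene lay in 12:114000001-115000000, where 34.4 kb was covered. Genes of other annotated types were not counted in these windows, so that window is not shown to be free of genes. The share in the densest 5% of windows was lower in the single lists, at 32.5% of 30585 peaks in replicate 1 and 46.5% of 7719 in replicate 2. The windows were chosen by their own peak counts, and no share expected by chance was measured. Such a share can rise as a list gets shorter, so the lists cannot be compared in concentration by it.

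Between chromosomes, peak density varied from 6.99 per Mb on chromosome 7 to 0.514 per Mb on X among the autosomes and X. Chromosome 7 had 3.03 times the density of the whole set, with 992 peaks, chromosome 17 had 2.47 times, with 523 peaks, and chromosome 18 had 1.82 times, with 367 peaks. Chromosomes 4 and 13 had 1.5 and 1.48 times. The X chromosome held 84 peaks, 0.222 times the density of the whole set, and Y held 3. Density is per called base, without correction for chromosome copies in the mixed-sex pools or for where reads can be placed. Low values on X and Y are therefore not evidence of less of the mark there. Chromosomes 7 and 17 were also the densest in each replicate's own list. The replicates differed on X, where replicate 1 had 0.768 and replicate 2 had 0.235 times its own overall density.

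**Figure D4:**
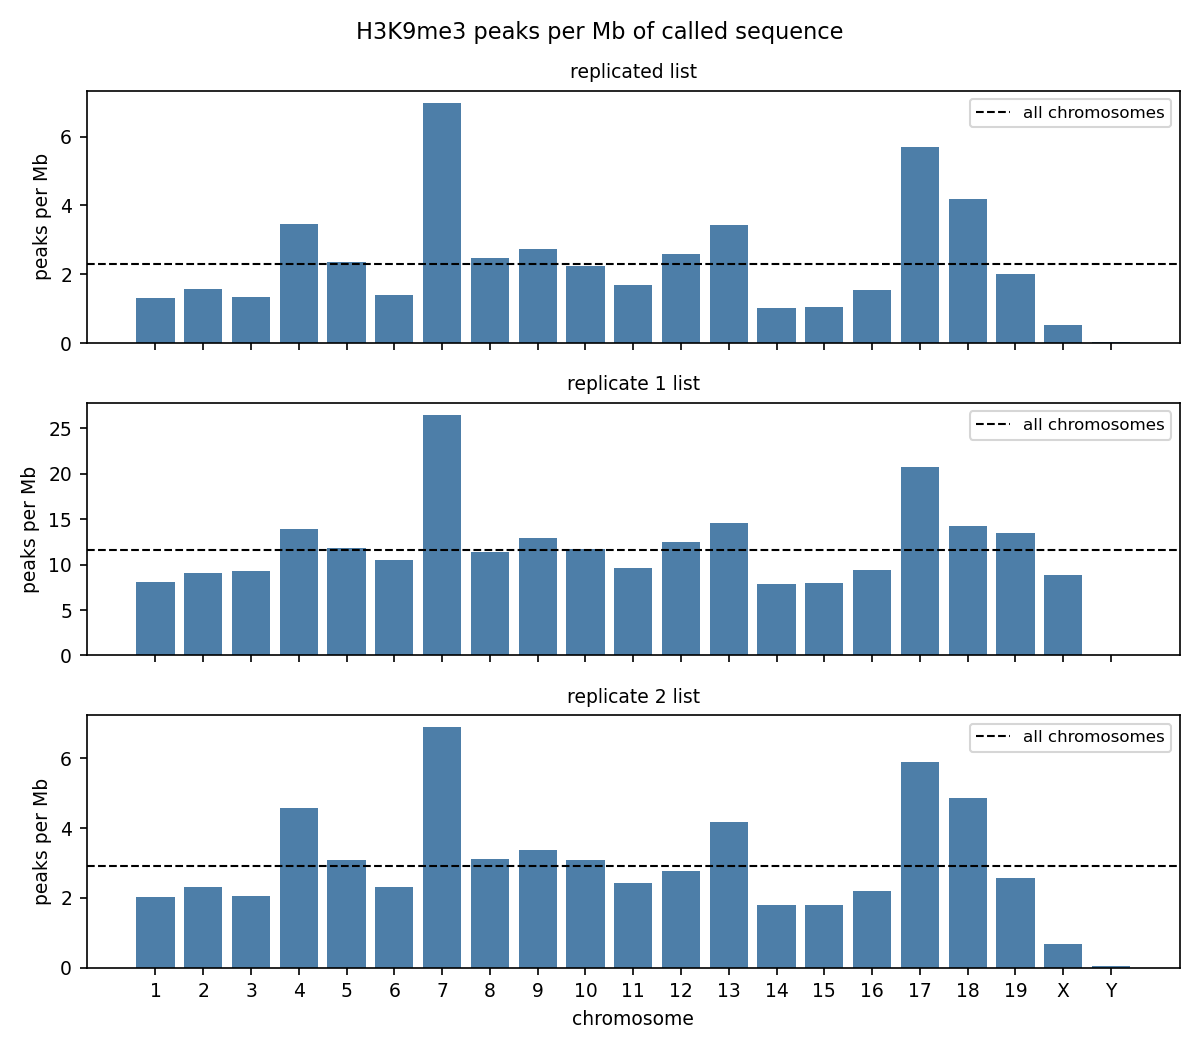
H3K9me3 peaks per Mb of called sequence on each chromosome, in the replicated list and in each replicate's own list (bars), with the density over all chromosomes as a dashed line. Chromosome 7 is highest in each panel, and X lies far below the line in the replicated list and in replicate 2 but closer to it in replicate 1.

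Summits were over-represented in exons and promoters and under-represented in introns. Exons held 7.11% of 6119 summits (exact 95% interval 6.48 to 7.78%) against 2.67% by chance (2.66-fold, p = 0.0002), and promoters, within 2 kb of a protein-coding TSS, 5.26% (4.72 to 5.85%) against 3.48% (p = 0.0016). The exon excess was smaller in replicate 1's own list, at 4.20% of summits (1.63-fold), than in replicate 2's, at 6.71% (2.56-fold). Introns held 26.5% (25.4 to 27.6%) against 36.5% (permutation p = 0.0002). The share outside protein-coding genes, 61.2% (59.9 to 62.4%), did not pass against 57.4% by chance (permutation p = 0.129). It did in replicate 1's own list (63.4% against 57.8%, permutation p = 0.0002) and in the pooled list (64.4% against 57.4%, p = 0.0002), and not in replicate 2's (60.2%, p = 0.158). The p of 0.0002 is the smallest that 10000 rotations can give, and these 4 p-values were not adjusted. Without summits inside Zfp-named and protocadherin genes, a restriction added after the data were seen, exons stayed above chance (4.34% against 2.68%, permutation p = 0.0002). Promoters did not pass, with 213 of their 322 summits left (3.85% against 3.49%, permutation p = 0.432). Rotated summits could still land in the removed genes, so the removal lowers the promoter ratio in part by construction. The share outside genes is not compared here, since removing summits inside genes raises it.

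The sequence under the peaks was richer in G and C and poorer in soft-masked sequence than chance placement. The mean GC content was 44.9% against 42.1% ± 0.343 (SD over 1000 rotations). The soft-masked share, the bases that the genome sequence gives in lower case as repetitive, was 22.4% against 33.9% ± 0.972. No repeat annotation was read, so kinds of repeat were not told apart. Both had permutation p = 0.002, the smallest that 1000 rotations can give. Replicate 1 had 45.0% GC and 22.1% soft-masked sequence, and replicate 2 had 44.5% and 23.0%.

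Both replicates marked overlapping regions far more often than chance gave, although most peaks of either list had no counterpart. Of 30585 placed peaks of replicate 1, 2989 (9.77%) shared at least 1 bp with a peak of replicate 2, against 0.195% by chance. Of 7719 peaks of replicate 2, 2921 (37.8%) overlapped replicate 1, against 0.770%. The Jaccard index of covered sequence was 0.0825 against 0.000854. These shares depend on list length: with 7719 peaks in each list they were 20.5% of replicate 1 and 21.2% of replicate 2, with a Jaccard index of 0.121. Each value had permutation p = 0.0002 by rotation. Peaks with a q of at most 1% were shared more often, at 46.8% (44.2 to 49.4%) in replicate 1 and 72.0% (69.1 to 74.9%) in replicate 2, than weaker peaks, at 7.93% (7.62 to 8.25%) and 33.0% (31.9 to 34.2%). That compares with the other replicate's full list; with both lists at a q of at most 1%, 23.8% of replicate 1 and 34.6% of replicate 2 were shared. Across 2687 shared regions, which are not independent replicates, Spearman's rho of fold enrichment was 0.210 (95% block bootstrap interval 0.151 to 0.268). In the replicated list, 73.8% of peaks were covered for at least 50% of their length by replicate 1's peaks and 52.9% by replicate 2's. Both held for 35.3% (34.1 to 36.4%), so most peaks of that list were not covered to that extent in both replicates' own lists. With 1 shared bp, 46.0% were found in both.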

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

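Some peaks lay on sequences that no comparison with chance placement used. Of the 6326 replicated peaks, 207 (3.27%, exact 95% interval 2.85 to 3.74%) lay on 18 unplaced or unlocalised sequences of the assembly. They were flagged because there were no control samples and the count is above the 3 that a count of 0 allows. No number expected by chance was measured, so this shows only that peaks were listed there. The most were on Un_JH584304 (49 peaks over 30257 bp, median fold 2.93), Un_GL456393 (35 peaks, 3.79) and Un_GL456383 (24 peaks, 3.74). The same sequences held 54, 50 and 28 peaks in replicate 1's list and 55, 38 and 26 in replicate 2's. The highest −log10 p of the replicated list, 83.9, was on Un_JH584304 at a fold of 3.96. No technical or biological explanation was tested. With 2 replicates in 1 group, no replicate could be tested as standing apart, and there was no second group to differ from.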

How the results depend on the processing

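Settings called peaks in both lists, and without Zfp or protocadherin summits, were added after the data were seen; the others were fixed before. Replacing the replicated list by the other replicate's own list stands for leaving a replicate out. Of 141 values under alternatives that answer a comparison, 104 kept their direction and side of the threshold or stayed within their interval, 28 moved, 4 were weaker, 2 stronger and 3 reversed. The protocadherin and imprinted lists, replicate overlap, summits in exons and introns, the Zfp position, GC and soft-masked shares kept their calls under every alternative run. Merging overlapping rows changed nothing, since no list had any. The cause of these changes was not tested.

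At a q of at most 1%, by construction fewer peaks remained: 1611 in replicate 1, 1086 in replicate 2, 2571 pooled and 2206 replicated. Chromosomes 7, 17 and X then held 14.2%, 9.57% and 1.82% of peaks (16.2%, 8.55% and 1.37% in the replicated list), the densest 5% of windows 71.8%, and the ratio to chance of summits outside genes was 0.954. Vomeronasal receptors fell to 2.68 times chance. The ratios of taste receptors, beta-defensins, killer cell lectin-like receptors and germline genes were all 0.

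For each replicate's own list, shares ranged from 12.3 to 12.7% on chromosome 7, from 6.21 to 7.0% on chromosome 17 and from 1.45 to 4.74% on X, with 32.5 to 46.5% in the densest windows. The ratio of summits outside genes was 1.05 to 1.10, past the threshold in replicate 1's list alone (permutation p = 0.0002, against 0.158). Lists that changed side of 1, none past the threshold, were Rhox (0 to 1.32), Pramel (4.84 to 10.4), neuronal (0.849 to 1.07), blood (0.967 to 1.69), endothelial (0.980 to 1.94), liver (0.679 to 2.56) and housekeeping (0 to 1.21).

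In the pooled list, chromosomes 7, 17 and X held 15.2%, 7.57% and 1.72%, and ratios were 2.41 for Rhox, 5.41 for Pramel, 1.05 for neuronal and 0.717 for muscle genes. Among peaks in both lists, chromosome 7 held 15%, the densest windows 67.9%, summits outside genes were at 0.978 times chance and H3K9 machinery at 1.46. Without Zfp or protocadherin summits, promoters fell to 1.10 times chance, in part by construction, and did not pass (permutation p = 0.432). The ratio outside genes was 1.18, which the removal of summits inside genes raises by construction.

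Within 2 kb of the TSS, the Zfp-named ratio was 0.997 and the vomeronasal 3.14. Zscan and Zkscan, endothelial and muscle genes were at 0, and H3K9 machinery at 4.55. With the 1000 peaks of highest fold, vomeronasal receptors were at 2.91, and Zscan and Zkscan, taste receptor, beta-defensin, killer cell lectin-like and germline genes at 0. With length-matched random genes 7 lists lay above chance in place of 4, the others being olfactory, killer cell lectin-like and cytochrome P450. That test, like Fisher's, treats neighbouring genes as independent. Fisher's exact test put 1 list below others, the olfactory receptors at 0.639, with beta-defensins at 0.868 and liver markers at 0.912. Windows of 500 kb put 62.7% of peaks in the densest 5%. Rho was 0.288 on −log10 p. The share of peaks in both replicates' lists rose to 46.0% (1 bp) and 44.9% (50% of either peak) for the replicated list and to 16.7% and 15.8% for the pooled list, from 35.3% and 12.4%. The depth of the libraries is unknown, which limits what the absence of a peak can show.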

Other observations

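The tests in this part were chosen after the result was seen, except the 2 tests of the soft-masked share, whose outcomes had not been seen.

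Several gene arrays outside the fixed lists carried the mark. Groups of 5 or more genes with one symbol stem and at most 500 kb between neighbours, chosen after the dense windows were seen, made up 112 arrays with 1037 genes. All 9 Ugt genes at 1:88055388-88220002 had a replicated peak, although these genes overlap and share peaks, while none of the 10 Ugt genes at 5:86889767-87490871 did. Of other arrays, 5 of 5 Ceacam genes (7:17713238-18077986), which encode cell adhesion proteins, 7 of 11 Skint genes (4:111919392-114245028), 6 of 29 Scgb genes (7:31290508-34100837) and 4 of 6 Mrgprb genes (7:48167983-48643811) had one.

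The idea that such families hold the mark was tested in 3 ways, each later one chosen after the one before it. The first tested each of 334 symbol stems with 8 or more genes alone, against 100000 rotations. In that scan 0 families passed, with a smallest p of 0.00416 for Nlrp genes (8 of 17 with a peak, permutation, adjusted p = 1). Ceacam, Scgb, Skint and Ugt genes had unadjusted p of 0.00786, 0.0252, 0.0313 and 0.0321, so none of these families stands on its own. An earlier run of this scan with 10000 rotations had the same outcome.

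The second test pooled the 1037 genes of all 112 arrays. Of these, 51 had a peak against 26.9 by chance (14 to 44 in the central 95% of rotations, permutation p = 0.0082). It decides nothing, because the Ugt and Ceacam arrays of the dense windows prompted it and were in it. The third left out these 2 arrays. Of the remaining 1023 genes, 37 had a peak against 25.9 by chance (14 to 42, permutation p = 0.159), so an excess beyond the arrays of the dense windows was not shown. The arrays were left out because of their peaks, while the rotated peaks kept those dense clusters. The third test therefore leans toward no excess and does not exclude one. Of the 112 arrays, 93 had no gene with a peak.

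The soft-masked share of replicated peaks, 22.4%, was below the 33.9% of chance placement, although H3K9me3 is known from repeats. If reads inside repeats had been lost in mapping and peaks called beside them, the 500 bp on either side of the peaks would hold more soft-masked sequence than chance. They held 32.1%, just below the 32.2 to 35.8% of rotations, which argues against it in that form. Peaks with summits outside exons and promoters still had 23.5% (chance 32.2 to 35.8%), so exons and promoters were not the whole reason. Loss of reads confined to the repeats themselves, which would leave the flanks unchanged, stays open, since the treatment of reads with several matches is not given. No biological explanation was tested.

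The X chromosome held 4.74% of replicate 1's peaks (exact 95% interval 4.51 to 4.99%) but 1.45% of replicate 2's (1.2 to 1.74%). At a q of at most 1% the shares were 2.62% (1.86 to 3.58%) and 2.21% (1.37 to 3.36%), which is consistent with weak calls near the threshold making the difference, although only 38 and 21 such peaks lay on X. A longer list was not the whole reason, since replicate 1's top 7719 peaks by −log10 p still had 2.15% on X, above replicate 2's upper bound. The outside files used for calling differed between the replicates, and their part is untested. The labels describe both pools as mixed in sex, and no biological explanation was tested.

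Of the 6326 replicated peaks, 3486 (55.1%) did not share 50% of either peak with both replicates' own lists, and their median fold was 3.26 against 3.62 for the rest. Weak calls alone did not account for this: at a q of at most 1% the share found in both was 71.2% (69.2 to 73.1%), above the 30.8% (29.4 to 32.3%) of weaker peaks but short of the 90% set for that explanation. All 2840 pooled peaks that met the criterion were in the replicated list, and the further 3486 were too. This is consistent with a rule of the authors that takes in more than overlap with the 2 replicate lists. The name of the list is therefore not evidence that a given peak was called in each replicate.

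The peaks of highest −log10 p were not those of highest fold. Those on the unplaced sequence Un_JH584304 had 83.9 and 76.3, at folds of 3.96 and 3.48. A peak at 17:39843009-39846780, overlapping Gm26917 and CT010467.1, had a −log10 p of 80.5 at a fold of 2.84. A pair at 11:3195290-3197140 and 11:3197505-3198637, overlapping Drg1, had 77.6 and 77.0 at 3.30. No peaks were filtered out as possible artefacts, so a high −log10 p at such a fold does not show a mark specific to these genes.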
